A study of Mus musculus with 24 samples.

How the data were processed

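The series covers 24 samples of mouse embryonic stem cells and derived lines, of which 4 chromosome conformation capture carbon copy (5C) libraries were analysed. The other 20 samples, from CTCF ChIP-seq, RNA-seq, single-cell RNA-seq and Hi-C, were not analysed here. The 4 libraries came from E14Tga2 cells, a mouse embryonic stem cell line, grown per the labels' protocols with LIF, 1 μM of a MEK1/2 inhibitor and 3 μM of a GSK3 inhibitor, and fixed with 2% formaldehyde. Each condition had 1 library: a DMSO control, transcriptional inhibition (TI), a mock treatment and an RNase treatment. The 5C labels do not state the drug, the dose or the duration of TI, nor the RNase used.

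In 5C, restriction fragments that were cross-linked and ligated are read out with forward and reverse probes, so that each value belongs to a pair of 1 forward and 1 reverse fragment. The authors deposited each library as a matrix of read counts, which were whole numbers with a different total per library and were therefore taken as not normalised. Per the file headers, the fragments were HindIII fragments on chromosome 6 with mm9 coordinates, and the probe set was named for the HoxA topologically associating domain (TAD). Per the submitters' processing notes, Bowtie 1 was used and the build was mm10. The headers name mm9, so all positions are given in mm9 as in the files, 1-based, and none was converted. How duplicate reads, multiple matches and probe failures were treated is not given in the sources used here, nor is whether material was pooled.

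The matrices held 479 forward and 480 reverse fragments, hence 229920 pairs, from 50194861 to 53999559. Total read counts were 12269160 for DMSO, 10101659 for TI, 10536973 for Mock and 12050564 for RNase. Positive counts at distances over 1 Mb clustered around 19, 11, 14 and 9 reads respectively, as amplified copies of single ligation products would. Dividing the totals by these numbers gave about 645745, 918332, 752640 and 1338951 ligation products. Intervals of shares (95%, Wilson) and of ratios (95%, log normal) were computed on these estimated products and cover counting error only. They do not cover the variation between cultures or library preparations, which 1 library per condition leaves unmeasured. Intervals of medians over contacts (95%, order statistics) treat contacts as independent, which contacts that share a bin are not. They describe the spread over contacts and no error between libraries.

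Probes with under 1000 reads in any library (5 forward and 9 reverse) were treated as missing. Fragment pairs were averaged in pairs of 20 kb bins with at least 4 fragment pairs each, which gave 16342 bin contacts at least 20 kb apart. The bin size, this minimum and the probe filter were set after the sparsity of the counts was seen and before any comparison was computed. All other main settings, the rule for named items and the alternatives were fixed before the data were examined, except where stated. Observed/expected was the mean read count of a bin contact over the mean at the same distance in the same library, with a pseudocount of 1 read on both. Strong contacts had an observed/expected of at least 2 in the control library of the other arm (Mock for TI, DMSO for RNase), so that the library used for choosing was no part of the comparison. The long-range share was the percentage of reads at 20 kb or more that lay beyond 250 kb. The insulation score was the log2 mean signal across a bin in a window of 200 kb, relative to the mean over the region. Boundaries were local minima with a depth of at least 0.2, again taken from the other arm's control, and the within-domain share was the percentage of reads at 20 kb to 1 Mb that joined fragments between the same boundaries. The 10 single domains were an exception: their limits were the minima of Mock that all 4 libraries shared, so for RNase vs Mock they came from a library under comparison, and they were recomputed with limits from DMSO after the data were seen. Changed contacts had a treated/control ratio of observed/expected of at least 2-fold in either direction.

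With 1 library per condition no test across conditions was possible and no p-value was computed. Medians of sets of contacts were placed among 10000 random sets of the same size matched on distance, and, as an addition made after the data were seen, on distance and mean signal. The mean signal was that of the 2 libraries under comparison, so this matching is not independent of their ratio. Ranges given for random sets hold the central 95% of their medians, while those for simulated libraries run from the lowest to the highest value. Chance in the draw of ligation products was measured with 100 simulated sets of libraries drawn from 1 profile shared by both libraries of an arm. Each product of a library was given the same number of reads. The simulated ranges therefore leave out variation in amplification and between preparations. In simulated data for TI vs DMSO, 200 planted 4-fold changes among 16342 contacts were called at the 2-fold limit in 95.5% of cases and 2-fold changes in 47%. The respective shares for RNase vs Mock were 95.5% and 47.5%. Planted falls to 0.25 of the control level were called in 74.5% (TI vs DMSO) and 85% (RNase vs Mock).

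Named items followed a rule fixed in advance: per comparison the 8 largest decreases and 8 largest increases among strong contacts, the 3 loci with the lowest and the 3 with the highest median ratio over contacts up to 1 Mb, and up to 6 of the deepest boundaries. Of the contacts, 3 in each direction are given singly and the others as a range. The boundary at 52.56 Mb and the single domains were named after their values were seen. Gene positions in mm9 were not used here. The order of genes was taken from a RefSeq table of GRCm38.p6, from which no coordinate was used. The planned analysis of CTCF motif orientation needs the genome sequence of the files' build and was not run.

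Alternatives were other thresholds, other choosing libraries, a median expected value, balancing of rows and columns, a pseudocount of 5, contacts above 0 in all 4 libraries, other distance limits, loci without the lowest 10%, insulation windows of 100 and 400 kb and the own control's boundaries. Alternatives added after the data were seen left out 324 outlier fragment pairs (0.141% of pairs, each over 30 times the median positive count at its distance in some library), or used 40 kb bins or single fragment pairs. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.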

Results

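The study asked how RNA bears on the function of CTCF, a zinc-finger DNA-binding protein found at many domain boundaries and loop anchors. The part analysed here measured chromatin contacts around the HoxA cluster in mouse embryonic stem cells in which transcription was inhibited or RNA was digested. The 5C probes covered 3.80 Mb of chromosome 6 (mm9, 50194861 to 53999559). In the GRCm38.p6 gene order, the 11 Hoxa genes, which encode homeodomain transcription factors that pattern the body axis, are preceded by Nfe2l3, Hnrnpa2b1, Cbx3, Snx10 and Skap2. They are followed by Evx1, Hibadh, Tax1bp1, Jazf1, Creb5 and Tril. Results are given by mm9 position, not by gene. There was 1 library for each of 4 conditions, so differences are between libraries and have no replicate error.

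The libraries held 10101659 to 12269160 reads. No reads were counted in 48.7% of fragment pairs in DMSO, 40.1% in TI, 39.9% in Mock and 28.7% in RNase. All 4 libraries showed the same 9 insulation minima within 60 kb, at 50.54, 51.14, 51.44, 51.80, 52.20, 52.56, 52.96, 53.44 and 53.70 Mb, which divided the region into 10 domains. Insulation profiles over 171 bins correlated across bins at r = 0.990 between Mock and RNase and at 0.987 between TI and Mock, but at 0.811 between TI and DMSO and 0.796 between DMSO and Mock. Without the outlier pairs described below, these values were 0.991, 0.984, 0.919 and 0.918. Bins are not independent replicates. A few fragment pairs took a large part of the DMSO library: 324 outlier pairs carried 21.0% of its reads at 20 kb or more, against 5.97% in TI, 6.49% in Mock and 5.55% in RNase. The pair of fragments at 51444693 to 51447405 and 51638011 to 51639406, 193 kb apart, had 293176 reads in DMSO, 58250 in TI, 47262 in Mock and 53218 in RNase.

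RNase against mock treatment addressed whether contacts around HoxA differ after RNA is digested. Contacts within domains took a smaller share of reads in the RNase library than in Mock. The within-domain share was 45.2% (95% interval 45.1 to 45.3) in RNase and 47.2% (47.0 to 47.3) in Mock, a difference of −1.96 percentage points. Of the 10 domains, whose limits were minima of Mock itself, 9 held a lower share of reads in RNase, with a log2 ratio down to −0.15 in the domain from 53.44 to 53.70 Mb. The exception was the domain from 51.80 to 52.20 Mb, with a log2 ratio of 0.0072 (95% interval −0.0089 to 0.023). Among the 9, the domain from 51.14 to 51.44 Mb had an interval that included 0 (−0.025, −0.056 to 0.0059). Between neighbouring domains the share was higher across 6 of 9 boundaries, most across 51.44 Mb (0.15, 0.12 to 0.18), 52.56 Mb (0.12, 0.10 to 0.14) and 51.80 Mb (0.12, 0.097 to 0.14). It was lower across the boundary at 52.20 Mb, with a log2 ratio of −0.13 (−0.16 to −0.094). With the same boundaries at their positions in DMSO, the counts stayed at 9 of 10 domains lower and 6 of 9 boundaries higher. With all 12 boundaries of DMSO as limits, 11 of 13 domains held a lower share in RNase, but the share across boundaries was higher at only 7 of 12, or 6 of 12 without outlier pairs. The 2 control libraries differed by 0.189 points in the within-domain share, and by 3.80 points without outlier pairs, where RNase and Mock differed by −2.01.

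**Figure D1:**
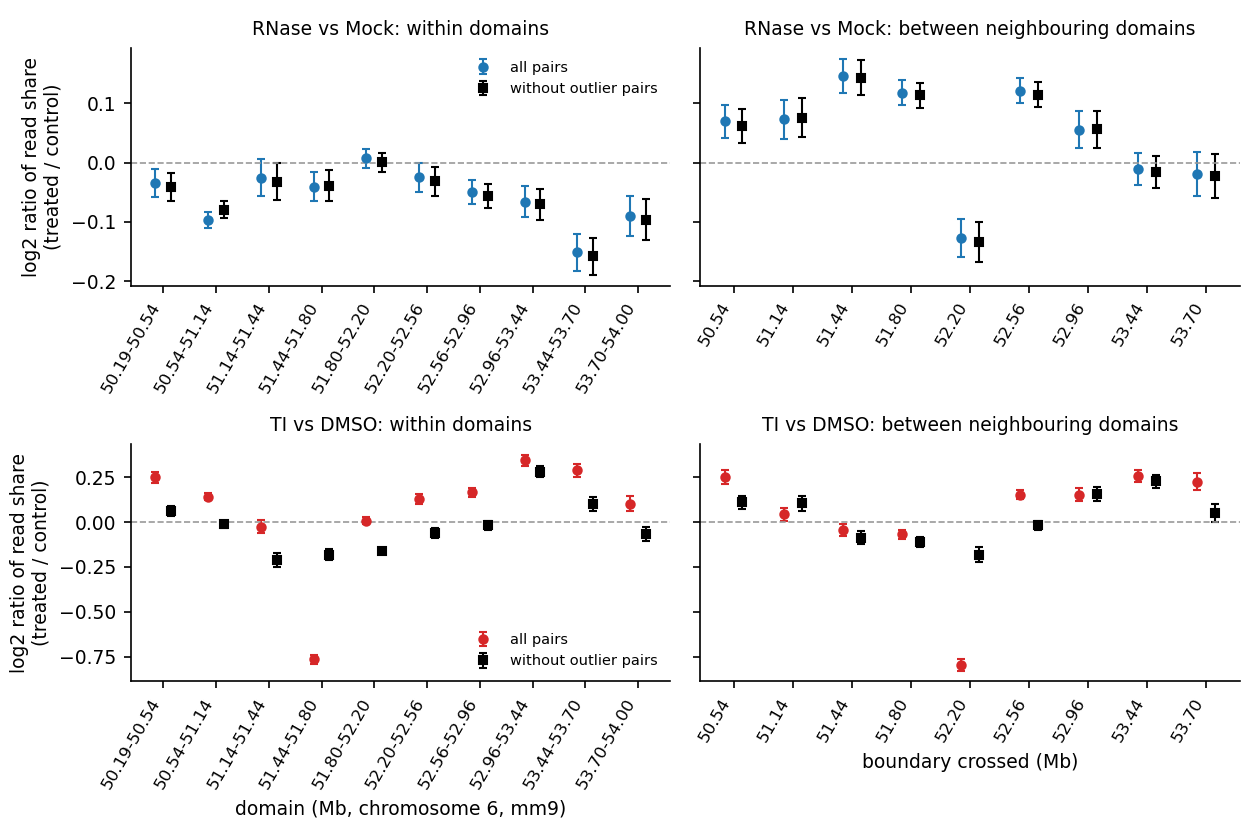
Log2 ratio (treated/control) of the share of reads at 20 kb to 1 Mb, within each of the 10 domains (left) and between neighbouring domains across each of the 9 boundaries (right), for RNase vs Mock (top) and TI vs DMSO (bottom). Circles are all fragment pairs, squares leave out the 324 outlier pairs and bars are 95% counting intervals. In RNase vs Mock, 9 of 10 domains lie below 0 and 6 of 9 boundaries above it.

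The difference followed distance. Scaled reads per fragment pair in RNase were 0.884 times those in Mock at 20 to 50 kb (95% interval 0.876 to 0.891) and 0.970 times at 50 to 100 kb (0.961 to 0.978). They were 1.05 times as high at 250 to 500 kb (1.04 to 1.06) and at 500 kb to 1 Mb (1.04 to 1.06), and 0.984 times at 2 to 4 Mb (0.968 to 1.00). Shares within and between domains are parts of 1 total and were not corrected for distance. The lower shares within domains and the higher shares between them therefore cannot be told apart from this course with distance. The controls differed from each other by distance as well. At 20 to 50 kb the scaled values were 37.0 in RNase, 41.9 in Mock and 37.5 in DMSO. Without outlier pairs they were 39.2, 44.8 and 47.5. The share beyond 250 kb was 49.9% (49.8 to 50.01) in RNase and 48.5% (48.4 to 48.6) in Mock, 1.41 percentage points higher. This share was 50.05% in DMSO, so the 2 control libraries differed by 1.54 points, and without replicates a difference of this size cannot be assigned to the treatment. The difference between RNase and Mock was 0.465 points at a limit of 500 kb and 0.511 for contacts at least 50 kb apart.

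**Figure D2:**
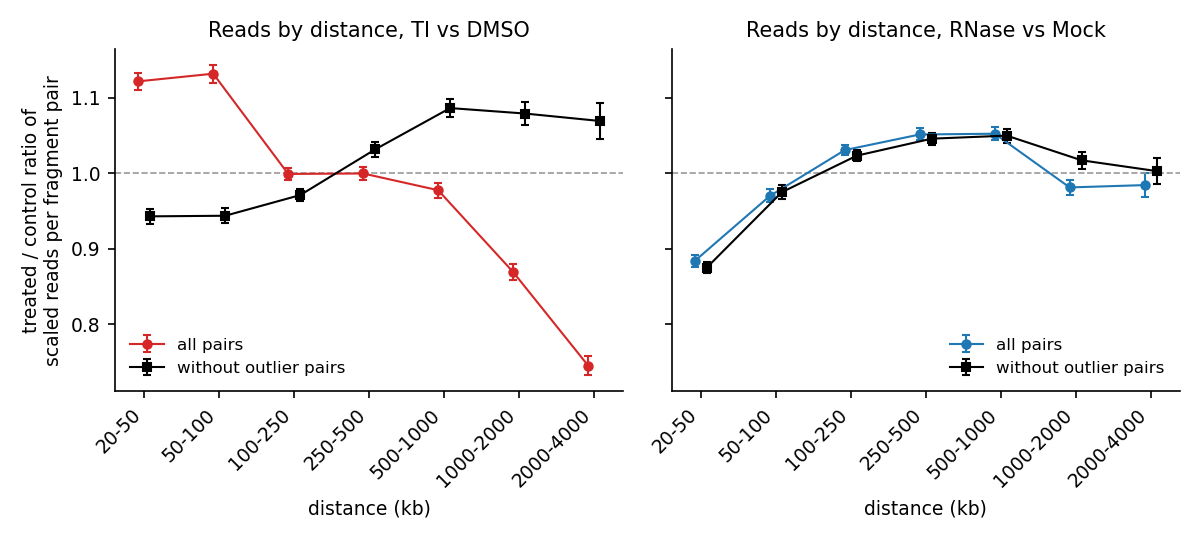
Ratio (treated/control) of scaled reads per fragment pair by genomic distance (kb) for TI vs DMSO (left) and RNase vs Mock (right), with 95% counting intervals. Circles are all fragment pairs and squares leave out the 324 outlier pairs. RNase lies at 0.884 of Mock at 20 to 50 kb and at 1.05 at 500 kb to 1 Mb, while the course for TI turns over when outlier pairs are left out.

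Insulation scores at the boundaries moved in no common direction in the RNase library. Over the 12 boundaries of DMSO the median change in insulation score was 0.0046 (range −0.13 to 0.15), and 7 of 12 scores were higher. The 12 include minima at 50.76, 50.88 and 52.12 Mb that had no match in Mock or RNase within 60 kb. The deepest boundary, at 50.54 Mb, had an insulation score of −1.20 in Mock and −1.19 in RNase, and that at 51.12 Mb −1.31 and −1.27. Scores were higher, meaning weaker insulation, at 51.80 Mb (−0.42 in Mock, −0.28 in RNase) and 52.56 Mb (−0.12 and 0.029). At 52.20 Mb (52194861 to 52214860) the score was lower, −1.12 in Mock and −1.25 in RNase. The remaining named boundaries changed by −0.049 (53.70 Mb) and 0.034 (52.96 Mb), within the spread over all 171 bins (SD 0.071). Depth at the minima shared by all libraries was lower in RNase than in Mock, for example 1.83 and 1.96 at 50.54 Mb. It was higher only at 52.20 Mb (2.01 and 1.90) and 53.70 Mb (1.03 and 1.02).

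**Figure D3:**
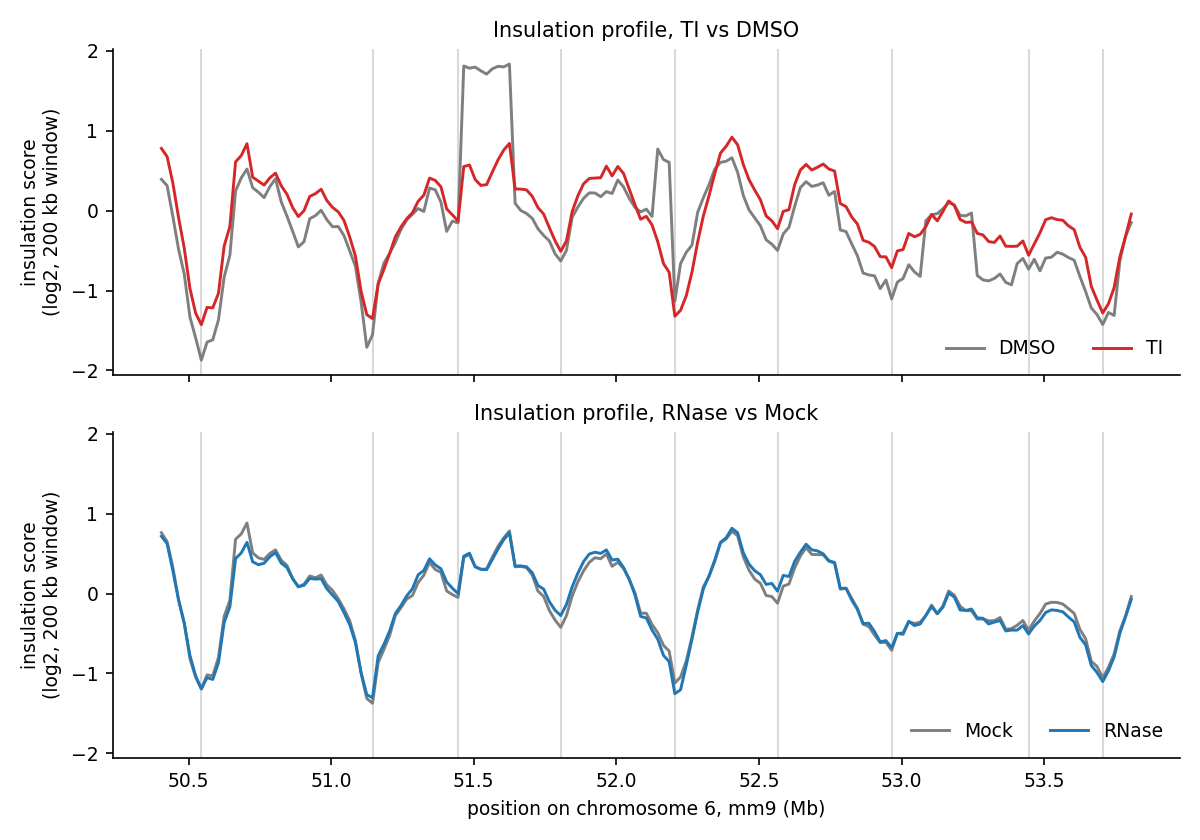
Insulation score (log2 mean signal across each 20 kb bin in a 200 kb window, relative to the region) along chromosome 6 in mm9 (Mb), for TI and DMSO (top) and RNase and Mock (bottom). Grey vertical lines mark the 9 boundaries found in all 4 libraries. Mock and RNase follow each other closely, with r = 0.990 over 171 bins, and DMSO departs from TI in plateaus.

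Strong contacts were slightly weaker in the RNase library. Over 744 strong contacts the median log2 ratio was −0.059 (95% interval of the median −0.080 to −0.034), with 431 contacts lower and 313 higher. Distance-matched random sets had medians of −0.021 to 0.049 (central 95%), which placed the strong contacts at percentile 0.01, but sets matched also on mean signal placed them at percentile 3.76. At a limit of 1.5-fold 62 strong contacts were lower and 44 higher, but at 2-fold 15 were lower and 20 higher, and without outlier pairs 148 were lower and 147 higher at 1.5-fold. In that set the median was −0.021 (−0.059 to 0.00086, 1255 contacts), at percentile 77.6 of sets matched on distance and mean signal. Across all 16342 contacts, 815 were at least 2-fold lower and 1266 at least 2-fold higher. Simulated libraries drawn from 1 shared profile gave 721 to 830 lower and 995 to 1178 higher contacts. Only the higher contacts lay above the simulated range. The simulation held no variation in amplification or between preparations, so this excess cannot be told apart from either. The total of 2081 changed contacts compares with 5508 between the 2 controls.

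The loci with the lowest median ratios in RNase were 52694861 to 52714860 (log2 −0.18, 48 of 77 contacts lower), 53994861 to 54014860 (−0.15, 10 contacts only) and 52174861 to 52194860 (−0.14, 69 of 98 contacts lower), the last next to the boundary at 52.20 Mb. The highest were 53794861 to 53814860 (0.24), 50194861 to 50214860 (0.22) and 53834861 to 53854860 (0.19). Among strong contacts the largest decrease joined 52194861 to 52214860, the bin of the 52.20 Mb boundary, with 52994861 to 53014860, 800 kb away, at 44.5 mean reads per fragment pair in Mock and 13.8 in RNase (log2 −1.98, 4 fragment pairs). Next were the contact of the bins starting at 51514861 and 52894861 (−1.78) and that of the bins starting at 51054861 and 52154861 (−1.76). The other 5 named decreases ranged from −1.66 to −1.28. At a pseudocount of 5 these decreases were −1.69, −1.28 and −1.41, and −1.27 to −0.78 for the other 5. The largest increases joined the bins starting at 51154861 and 52814861 (3.44, from 1.5 to 28.8 mean reads), 51894861 and 52994861 (2.09) and 51274861 and 52254861 (1.88), and the other 5 ranged from 1.45 to 1.75. With the higher pseudocount they were 2.28, 1.51 and 1.61, and 0.98 to 1.37. The contact of 51894861 and 52994861 held 1 outlier pair and was at 1.38 without it. Most of the named contacts rest on 4 to 16 fragment pairs with few ligation products, so single contacts are weakly supported.

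Transcriptional inhibition against DMSO addressed whether contacts differ when RNA synthesis is blocked. The locus with the lowest ratios lay at the 52.20 Mb boundary, where the insulation score was −1.14 in DMSO and −1.32 in TI. There 71 of the 90 contacts of the bin 52194861 to 52214860 up to 1 Mb were lower in TI. The median log2 ratio of the 90 was −0.45 (95% interval of the median −0.71 to −0.26), and −0.72 without outlier pairs. This interval treats contacts that share 1 bin as independent. The median over all contacts up to 1 Mb was 0.30 in TI vs DMSO. The share of reads between the domains on either side of 52.20 Mb was also lower in TI (log2 −0.79, and −0.18 without outlier pairs). With all pairs it held 1 fragment pair with 129322 reads in DMSO and 16521 in TI. Without outlier pairs, shares were lower within 7 of 10 domains and higher within 3. The lower ones included 51.14 to 51.44 Mb (−0.21), 51.44 to 51.80 Mb (−0.18) and 51.80 to 52.20 Mb (−0.16). The fall was therefore not particular to this boundary. Balancing rows and columns turned the median of the bin to 0.13, while the insulation change at 52.20 Mb stayed below 0 at −0.055. That change was −0.38 without outlier pairs, −0.37 with a window of 100 kb and −0.72 with a window of 400 kb, so its size depended on the setting. Of the windows used, only that of 400 kb takes in the fragment pair with 129322 reads in DMSO.

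The region-wide measures went opposite ways with and without the 324 outlier pairs. With all pairs, the share beyond 250 kb was 46.8% (46.7 to 46.9) in TI and 50.05% (49.9 to 50.2) in DMSO, a difference of −3.24 percentage points, and without outlier pairs it was 45.2% and 42.7%, a difference of 2.56. The within-domain share was 57.5% (57.4 to 57.7) in TI and 56.0% (55.8 to 56.1) in DMSO, 1.59 points higher, and without outlier pairs it was 58.3% and 59.98%, −1.67 points. Scaled reads per fragment pair at 20 to 50 kb were 1.12 times those in DMSO (1.11 to 1.13), or 0.943 times without outlier pairs (0.933 to 0.952). At 2 to 4 Mb they were 0.745 times (0.732 to 0.758), or 1.07 times without outlier pairs (1.05 to 1.09).

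Insulation scores at the 9 boundaries of Mock were higher in TI at 8, with a median change of 0.17 (range −0.19 to 0.44). The median over all 171 bins shifted by 0.22, so boundaries were not weaker than the rest of the region, and without outlier pairs the median change at boundaries was −0.039. Of the 6 deepest boundaries, that at 51.14 Mb had scores of −1.55 in DMSO and −1.35 in TI, that at 50.54 Mb −1.87 and −1.43, and that at 53.70 Mb −1.42 and −1.28. The scores were −0.63 and −0.51 at 51.80 Mb and −1.10 and −0.71 at 52.96 Mb. Without outlier pairs the change turned at 51.14 Mb (−0.039), 53.70 Mb (−0.10) and 51.80 Mb (−0.062), and was 0.20 at 50.54 Mb and 0.15 at 52.96 Mb.

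Strong contacts had a median log2 ratio of 0.15 in TI vs DMSO (0.082 to 0.22, 740 contacts, 314 lower and 426 higher), below the medians of distance-matched random sets (0.38 to 0.50) and above those of sets matched also on mean signal (−0.035 to 0.071). The sign turned in 6 of 11 alternatives, with a range of −0.69 to 0.49 over all 11. Without outlier pairs the median was 0.043, with an interval that included 0 (−0.014 to 0.087). Of 16342 contacts, 797 were at least 2-fold lower and 4474 at least 2-fold higher. Without outlier pairs the counts were 1406 and 2289. RNase against DMSO was split in the same way, with 865 lower and 4634 higher, or 1377 and 2417 without outlier pairs. The median log2 ratio over all contacts in TI vs DMSO was 0.46, or 0.092 without outlier pairs. With all pairs, simulated libraries gave 1108 to 1242 lower and 1481 to 1638 higher contacts. Both simulated libraries came from 1 shared profile and lacked that offset, so the split into lower and higher contacts cannot be read against them. Without outlier pairs the total of 3695 lay above the simulated 2668 to 2860, but below the 4021 between the controls DMSO and Mock. With all pairs the total of 5271 likewise lay below the 5508 between these controls. TI differed from Mock, the control of the other arm, at 2673 contacts, or 2586 without outlier pairs.

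Besides 52194861 to 52214860, the lowest loci in TI were 53734861 to 53754860 (log2 −0.37) and 51154861 to 51174860 (−0.36), and the highest were 51374861 to 51394860 (0.91), 52694861 to 52714860 (0.75) and 50674861 to 50694860 (0.65). After balancing, both low loci turned (0.039 and 0.055) and the high loci were at 0.26, 0.29 and 0.14. Among strong contacts the largest decreases joined the bins starting at 50594861 and 52774861 (−2.87), 50334861 and 51354861 (−2.48) and 51974861 and 52334861 (−2.44). Of these, the contact of 50334861 and 51354861 was at −0.27 without outlier pairs and that of 51974861 and 52334861 at 0.13, while that of 50594861 and 52774861 held no outlier pair but was at −1.27 with a pseudocount of 5. The other 5 decreases ranged from −2.43 to −2.35, but 4 of them held an outlier pair and were at −0.25, 0.26, 0.055 and −0.40 without it. The fifth, of 50194861 and 52814861, was at −0.85 with a pseudocount of 5. The largest increases joined the bins starting at 50194861 and 52374861 (4.46, from 0.50 to 18.5 mean reads), 50674861 and 53374861 (4.39, from 0 to 12.8 mean reads) and 50794861 and 53994861 (4.09), all over 2 Mb apart. Their size depended on the pseudocount, and at a pseudocount of 5 they were 2.64, 2.23 and 2.17. The other 5 increases ranged from 3.41 to 4.08, and at a pseudocount of 5 from 1.69 to 2.68.

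The log2 ratios of the 2 treatments, which share no library, were nearly unrelated across the 16342 contacts (Spearman 0.029, Pearson 0.020). Contacts are not independent replicates. Simulated libraries gave Spearman values of −0.024 to 0.023, so the observed value lay just above their range. Without outlier pairs the Spearman value was 0.014, inside the simulated range of −0.024 to 0.023. As a reference, the crossed pairing of TI/Mock with RNase/DMSO gave −0.093 and DMSO/Mock with TI/RNase gave 0.12. At the level of boundaries, 52.20 Mb was 1 of 9 at which both treated libraries scored below both control libraries, and 51.14 Mb was 1 of 9 at which both scored above. For 4 unrelated libraries 1 in 6 orders gives each pattern, or 1.5 of 9 boundaries, so neither count exceeded this reference. The reference is rough, because the libraries were not equally alike (insulation r = 0.990 for Mock and RNase, 0.796 for DMSO and Mock). Without outlier pairs both treated libraries scored below both controls again at 52.20 Mb, and above them at 52.96 Mb.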

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

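The tests of random ligation, of outlier fragment pairs and of library preparation were chosen after the results had been seen. The tests of chance in the draw of ligation products and of balancing at the 52.20 Mb boundary were set before their results were seen.

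With all fragment pairs and the main settings, the treatments differed from their controls in opposite directions in 3 measures, and these differences between treatments were not tested, since each rests on 1 library. The median log2 ratio of strong contacts was 0.15 in TI vs DMSO and −0.059 in RNase vs Mock. In 6 of 11 alternatives, however, the TI median was below 0 as in RNase. In the main setting both lay below distance-matched sets. Against sets matched also on mean signal, TI lay above (percentile 100) and RNase within (percentile 3.76). That signal came from the libraries under comparison, so these percentiles are no independent reference. The long-range share differed by −3.24 percentage points in TI and by 1.41 in RNase, and the within-domain share by 1.59 points in TI and by −1.96 in RNase.

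The lower long-range share in TI depended on outlier fragment pairs, since the difference turned from −3.24 to 2.56 percentage points when they were left out. A candidate explanation is therefore an excess of a few pairs in the DMSO library, 21.0% of its reads at 20 kb or more against 5.97% in TI. The DMSO library also differed more widely. Its log2 probe totals correlated at 0.837 to 0.880 with the other libraries, against 0.976 to 0.994 among those. Without outlier pairs, observed/expected over bin contacts correlated at Spearman 0.492 to 0.520 with DMSO, against 0.580 to 0.639 among the others. Balancing, which kept the outlier pairs, also removed most of the difference, so unequal probe yield cannot be told apart from these pairs. Without these pairs TI and RNase differed from their controls in the same direction in both shares. That does not settle an effect of inhibition, because the control libraries then differed by −3.75 points (DMSO minus Mock) and TI minus Mock was −1.18 points. Whether inhibition changes the long-range share stays open.

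The higher long-range share after RNase did not follow from an even background of random ligation, which would raise the ratio most beyond 2 Mb. There the ratio was 0.984 (0.968 to 1.00), below the 1.05 found at 250 kb to 1 Mb. Outlier pairs were not the cause either, as the difference was 1.75 points without them, and 100 simulated library pairs gave at most 0.185 points by chance. A difference between single library preparations remains a possible explanation, since DMSO and Mock, which RNase does not separate, differed by 1.54 points. RNase treatment itself stays open as a biological explanation that 1 library per condition cannot separate from the preparation.

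Insulation at 52.20 Mb was deeper after both treatments, by −0.19 in TI and −0.13 in RNase, and 2 of 171 bins, that bin included, were as low in both, but in TI alone 18 were, or 34 after balancing, and in RNase alone 5. The smaller change was −0.14 without outlier pairs, so outlier pairs did not account for it. Simulated libraries reached no lower than −0.067 in RNase and −0.092 in TI at this bin. They did not repeat the choice of the boundary and gave every ligation product the same number of reads. Chance is therefore not excluded for a boundary picked for its low values. Differences between libraries stay open: without outlier pairs DMSO and Mock differed there by 0.19, more than RNase from Mock, against −0.015 with all pairs. After balancing, the change was −0.16 in RNase but −0.055 in TI, so for TI a part from unequal probe yield cannot be told apart from a local change, because the change there kept its sign but only part of its size. The boundary was singled out after its values were seen, and a treatment effect remains an untested hypothesis.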

How the results depend on the processing

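The alternatives without outlier pairs, with 40 kb bins and with single fragment pairs were chosen after seeing the data. RNase vs Mock kept its direction in strong contacts (11 of 11 alternatives, −0.17 to −0.021), long-range share (5 of 5, 0.465 to 1.75) and within-domain share (4 of 4, −2.08 to −1.82). For strong contacts this holds for the sign only, since without outlier pairs the interval of the median included 0 (−0.059 to 0.00086). TI vs DMSO kept no direction throughout in strong contacts, long-range share, boundary insulation or within-domain share. For the long-range share outlier pairs were tested as the cause, with 2.56 points without them. Causes for the other measures were not tested, except that contacts chosen in the own control carry that library's chance excess. The motif alternatives were not run. No paired analysis was possible because each condition had 1 library. Depth limits single contacts: in DMSO 67.6% of pairs over 1 Mb apart had no reads.

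Median log2 ratios of strong contacts in TI vs DMSO were 0.29 at a threshold of 1.5, −0.080 at a threshold of 3, −0.69 when chosen in the own control, −0.33 when chosen in both controls, −0.13 with a median expected value, −0.076 after balancing, 0.043 without outlier pairs, −0.053 with 40 kb bins and 0.49 with single fragment pairs. In RNase vs Mock they were −0.033 at a threshold of 1.5, −0.17 and −0.12 when chosen in the own control and in both, −0.029 at the higher pseudocount and −0.021 without outlier pairs. The long-range share in TI differed by −0.104 points after balancing, −2.72 for contacts at least 50 kb apart and 2.56 without outlier pairs. In RNase it differed by 0.465 at a limit of 500 kb, 0.511 for contacts at least 50 kb apart and 1.75 without outlier pairs. The within-domain share in TI differed by −0.681 after balancing, 0.949 with the own control's domains, 1.12 for contacts up to 500 kb and −1.67 without outlier pairs. The boundary change in TI was −0.0073 after balancing and −0.039 without outlier pairs, and in RNase −0.018 with a window of 400 kb. Changed contacts numbered 2852 (TI) and 598 (RNase) at the higher pseudocount, 8750 and 4804 at 1.5-fold, 969 and 110 of 4531 with 40 kb bins, and 109108 and 107335 of 220615 single fragment pairs. The shared change was 0.0113 after balancing, 0.0605 with 40 kb bins and 0.00745 with single fragment pairs.

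Some single boundaries, loci and contacts changed sign. After balancing, the boundary changes in TI were −0.16 at 51.44, −0.0073 at 51.80, −0.066 at 52.96 and −0.059 at 53.70 Mb, and in RNase −0.023 at 51.44 Mb. With a window of 100 kb they were −0.083 at 51.14, −0.17 at 51.44 and −0.14 at 53.70 Mb in TI and −0.036 at 50.54 Mb in RNase, and with a window of 400 kb −0.013 at 51.44 Mb in TI and −0.018 at 51.12 Mb in RNase. Without outlier pairs they were −0.039 at 51.14, −0.15 at 51.44, −0.062 at 51.80 and −0.10 at 53.70 Mb in TI and −0.0045 at 50.54 Mb in RNase. Balancing turned the medians of the loci starting at 52194861 (0.13), 53734861 (0.039) and 51154861 (0.055) in TI and 53994861 (0.028) in RNase. Without outlier pairs the TI contacts of 51974861 and 52334861 (0.13), 51274861 and 53914861 (0.26) and 50794861 and 53934861 (0.055) turned. Other named loci and contacts kept their sign in each alternative that gave a value.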

Other observations

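Short-range contacts, which entered no comparison, also differed between libraries: the share of reads from pairs under 20 kb apart was 30.3% in DMSO, 30.0% in TI, 26.2% in Mock and 23.0% in RNase. The fragments at 50252993 to 50253986 and 51638011 to 51639406, 1385 kb apart, had 53591 reads in Mock and 56776 in RNase and 0 in DMSO and TI, so this pair separated the arms and not the treatments. The reverse fragment at 50729504 to 50730212 took part in 2 of the pairs with most reads in TI. With the fragment at 50638395 to 50640949, 90.2 kb away, it had 45271 reads in TI, 27849 in DMSO, 47775 in Mock and 37453 in RNase.

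A hypothesis set before its result was seen was that contacts between domain boundaries, as anchors of CTCF loops would give, are lower after either treatment. The 36 contacts between boundary bins in TI vs DMSO had a median log2 ratio of 0.43, at percentile 33.1 of distance-matched sets. The 66 in RNase vs Mock had a median of −0.0032, at percentile 37.4. Neither lay below percentile 2.5, which by the rule set in advance counted against the hypothesis. The test could not decide, however, because these contacts were not clearly enriched in the controls to begin with. Their median observed/expected was 0.557 in DMSO (percentile 65.2 of distance-matched sets) and 0.888 in Mock (percentile 95.9), a check added after the data were seen. Boundary bins are 20 kb wide and were not checked for CTCF sites.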
